A study of Mus musculus with 16 samples.

How the data were processed

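Gene expression was measured by RNA sequencing in lymphatic endothelial cells sorted from the hearts of CD1 mice. Per the labels, surgery was a sham operation or a myocardial infarction (MI, ligation of a coronary artery) at postnatal day 1 (P1) or day 56 (P56), and hearts were taken 3 days later. The cells were sorted as negative for CD45, the leukocyte antigen, and positive for CD31 (the product of Pecam1) and podoplanin (the product of Pdpn). The 4 groups (sham P1, MI P1, sham P56 and MI P56) have 4 libraries each. Neonatal libraries came from pooled ventricles that were minced and digested in tubes, whereas adult hearts came from males and were digested by perfusion for a shorter time. Age is therefore tied to the digestion, the surgery, the pooling and the sex of the animals. The labels do not say how the pools or animals behind the libraries of a group relate to each other, so every p-value here measures the spread between these libraries.

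The deposited values are in the unit signal, 1 column per library, which the authors named CPM. Each value was a whole number of reads times 1 constant per library within a tolerance of 0.01 read, and the constants equalled edgeR CPM with TMM scaling to within 1.2e-07% of the value. The columns summed to between 297624 and 177049110, since the TMM factors, computed on the genes listed, ran from 0.00565 to 3.36. The design had assumed plain CPM. Per the submitters' processing notes, Trimmomatic, STAR, HTSeq and edgeR were used with the mm10 (GRCm38) genome. Whole read counts were recovered from the constants and used for depth, for edgeR and for DESeq2, and values below are given in the deposited unit. The table lists 15895 genes, of which 15871 had an identifier in the GENCODE M21 annotation and 13894 had the same coordinates there. The number of the table columns runs 1, 2, 3 and 5 in each group while the labels number each group 1 to 4, so the column numbered 5 of each group matches no label by its number, and its group was taken from the column name.

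The comparisons, the tests, the gene lists, the rule for named genes and most of the alternatives were fixed before the data were examined. Genes with a value of at least 1 in at least 4 libraries were kept, values were transformed as log2(value + 1), and limma-trend (limma 3.58.1 in R 4.3.3) was fitted to the 4 groups with all 16 libraries. Contrasts were MI against sham at each age, the difference between these responses (the interaction), and P56 against P1 in sham and after MI. A gene was called with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, two-sided. Changes on the log2(value + 1) scale understate the change of genes with low values. Tests with edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on the recovered reads were alternatives. The tests on 31 lists of genes (589 symbols, of which 501 were in the table and 88 were not) used camera with a preset correlation of 0.01 and again with an estimated correlation, with adjustment over all lists with 3 or more tested members. Counts of list members are given over all genes tested and adjusted over the list alone.

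After the values per library had been seen, a fit was added without the 3 libraries in which fewer than 10000 genes had a read. It has 13 libraries (2 sham P1, 4 MI P1, 4 sham P56 and 3 MI P56), and values are given from this fit, from that of all 16 libraries or from both, as stated with each. Named genes are, for each comparison and direction, the 6 with the largest change among those called, with a mean of at least 5 and with every library of 1 group above every library of the other (not asked of the interaction), leaving out predicted genes and pseudogenes. Where none was called, the 5 with the smallest p in each direction are given as values. Up to 4 members of each list with a called test or with at least 3 called members were added, as were 7 genes of the sort and of lymphatic identity. The same rule was used for the fit with 13 libraries, and some of the genes it names are not reported here.

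Other alternatives fixed then were a value of at least 5 in 4 libraries, no filter, pseudocounts of 0.25 and 4, median-of-ratios rescaling, quantile normalization, a fit of only the groups compared, weights per library, the replicate number as a block, and each library left out in turn. The method was tested on simulated data made from these values, with 200 changed genes per comparison. In the fit with 16 libraries it recovered 0%, 1.54% and 12.5% of genes changed 2-fold, 4-fold and 8-fold for MI against sham at P1 (13733 genes), 0%, 0% and 9.52% at P56 (13790 genes), 0% at each size for the interaction (13724 genes), 0%, 6.06% and 28.1% for age in sham (13742 genes) and 0%, 0% and 4.54% for age after MI (13728 genes), with 0 false calls for both comparisons of MI with sham. In the fit with 13 libraries the shares were 7.69%, 35.4% and 61.9% at P1 (13575 genes, 5 false calls), 8.96%, 52.3% and 73.0% at P56 (13622 genes, 7 false calls), 0%, 34.8% and 55.4% for the interaction (13558 genes, 7 false calls), 4.84%, 36.4% and 60.9% for age in sham (13587 genes, 4 false calls) and 10.6%, 51.5% and 72.3% for age after MI (13580 genes, 3 false calls). Errors are standard deviations (SD) of values or standard errors (SE) of log2 changes. Floors of 3 reads cover counting error only, since reads from amplified RNA without molecular identifiers are not independent molecules.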

Results

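The series asks how lymphatic endothelial cells of the heart respond to infarction at an age when the mouse heart regenerates and at an age when it scars. It holds 16 RNA libraries of sorted cardiac lymphatic endothelial cells, 4 each from sham and MI hearts at P1 and at P56, taken 3 days after surgery. Depth ran from 17103319 to 43837520 reads per library on the 15895 genes listed. Mitochondrial ribosomal RNA (mt-Rnr1 and mt-Rnr2) took 27.7% to 51.7% of the reads in 13 libraries, which had a read on 14121 to 15821 genes. In these, 6709566 to 12918569 reads lay on genes other than these RNAs and Uqcrc1, a gene described next.

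The other 3 libraries had a read on far fewer genes, 9451 in sham P1 library 1, 7939 in sham P1 library 2 and 7746 in MI P56 library 5. Reads on Uqcrc1, a subunit gene of mitochondrial complex III (chromosome 9, 108936633 to 108949623), made up 99.8% of MI P56 library 5 and 98.6% of sham P1 library 2. They made up 18.1% of sham P1 library 1 and 47.3% of sham P1 library 5, which kept reads on 15549 genes. Outside Uqcrc1 and the mitochondrial ribosomal RNA, MI P56 library 5 held 41346 reads, sham P1 library 2 held 321929 and sham P1 library 1 held 6376296. A count of 3 reads corresponded to a value of 12.9 in MI P56 library 5, 12.1 in sham P1 library 2 and 0.359 in sham P1 library 1, against 0.0489 to 0.109 in the others. Pairs of libraries within a group correlated across genes with r of 0.851 to 0.965 among the 13 libraries (16 pairs) and of 0.592 to 0.789 where at least 1 of the 3 was in the pair (8 pairs).

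**Figure D1:**
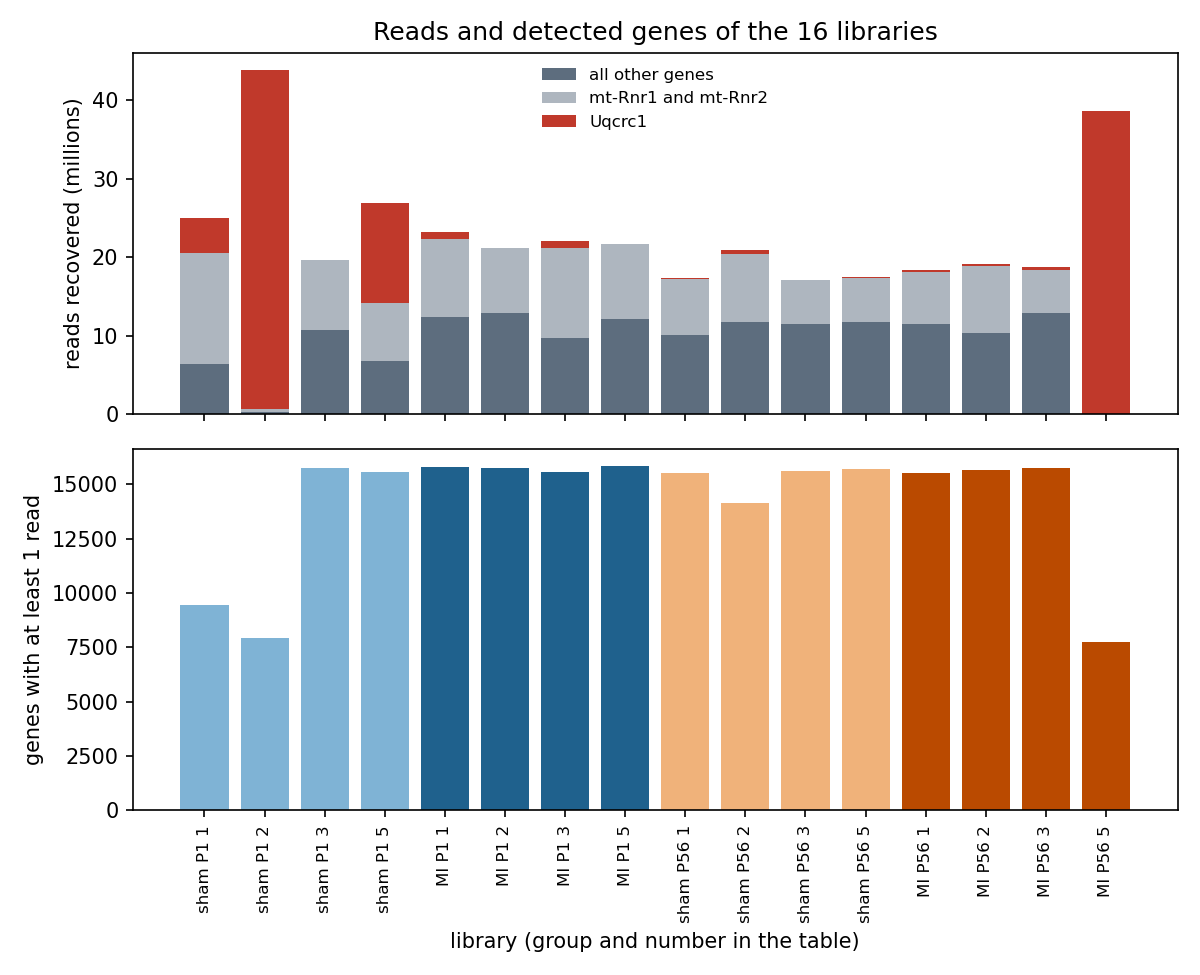
Reads per library (upper panel, stacked by other genes, mitochondrial ribosomal RNA and Uqcrc1) and genes with at least 1 read per library (lower panel). Uqcrc1 takes 99.8% of MI P56 library 5 and 98.6% of sham P1 library 2, and 3 libraries have a read on fewer than 10000 genes.

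Transcripts of the lymphatic lineage were abundant in all groups. Prox1, the transcription factor that specifies lymphatic endothelium, was at 371 ± 96.6 (SD, n = 2) in sham P1, 339 ± 137 (n = 4) in MI P1, 259 ± 70.7 (n = 4) in sham P56 and 189 ± 64.9 (n = 3) in MI P56, in the 13 libraries. The hyaluronan receptor Lyve1 was at 674 ± 117, 503 ± 121, 460 ± 125 and 423 ± 237 in the same order. Flt4, the receptor of VEGF-C and VEGF-D, was at 357 ± 112, 385 ± 41.4, 541 ± 220 and 417 ± 148. Of the sort genes, Pecam1 was at 98.4 to 141 and Pdpn at 14.4 to 17.7 as group means, and Thy1 (CD90), which is found on lymphatic endothelium and on fibroblasts, at 28.7 to 50.0. Ptprc, which encodes CD45, had means of 0.307 ± 0.281 in sham P1, 1.61 ± 1.25 in MI P1, 0.939 ± 0.416 in sham P56 and 3.21 ± 2.11 in MI P56. None of these 7 genes was called in any of the 5 comparisons, with 16 or with 13 libraries. Transcripts of other cell types were present too, such as titin (Ttn), a sarcomere gene of cardiomyocytes, at 1301 ± 382 in sham P56, and the fibroblast proteoglycan gene Dcn at 738 there.

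The comparison of MI with sham at P56 asks which transcripts differ 3 days after infarction of an adult heart. Tnc, which encodes the matrix protein tenascin C (chromosome 4, 63959785 to 64047015), went from 9.70 ± 3.37 (n = 4) in sham to 250.0 ± 152 (n = 4) in MI with all 16 libraries. Its log2 change was 4.43 ± 0.57 (SE; limma adjusted p = 9.3e-04), and 4.62 ± 0.31 with 13 libraries (adjusted p = 8.3e-08). Lox, the collagen cross-linking lysyl oxidase (chromosome 18, 52516069 to 52529867), went from 6.32 ± 2.85 to 130.4 ± 71.0 (4.09 ± 0.57, adjusted p = 0.0017). Col1a1 (collagen I; chromosome 11, 94936224 to 94953042) went from 147 ± 90.1 to 1302 ± 593 (3.24 ± 0.51, adjusted p = 0.0052), and Fn1 (fibronectin) from 123 ± 37.1 to 822 ± 369 (2.68 ± 0.39, adjusted p = 0.0017). Spp1 (osteopontin), made by macrophages and by injured tissue, went from 0.231 ± 0.247 to 28.3 ± 3.46 (4.59 ± 0.66, adjusted p = 0.0017).

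Of the 29 tested genes of the interstitial matrix list, 7 were higher, 0 lower and 22 not called with 16 libraries (16 higher when adjusted over the list alone). With 13 libraries 17 were higher and 0 lower (25 higher and 1 lower when adjusted over the list alone), with a list median of 1.63. This list was higher with a preset correlation, and with an estimated correlation its adjusted p was 0.0154 with 16 libraries and 0.0967 with 13. Postn (periostin; chromosome 3, 54361109 to 54391037) rose by 3.09 ± 0.51 on the log2 scale with 16 libraries (adjusted p = 0.0063), and without sham P56 library 5 it was at 2.94 (adjusted p = 0.0528). With 13 libraries Postn rose from 98.2 ± 61.3 to 928 ± 524 and kept its call without any 1 library. The same held for Col3a1 (304 ± 198 to 1452 ± 510), Col12a1 (2.94 ± 1.89 to 68.3 ± 46.3) and the protease inhibitor Timp1 (0.706 ± 0.386 to 28.7 ± 7.96). Cthrc1, a gene of collagen-producing repair cells, had 0 reads in 3 of 4 sham libraries and a value of 0.0170 in the other, against 16.6 ± 11.1 (n = 3) after MI. Of the 14 fibroblast genes, 5 were higher and 0 lower with 13 libraries (6 and 1 when adjusted over the list alone), 4 of the 5 being members of the matrix list as well. Dcn, a general fibroblast gene, was at 738 in sham and 613 in MI and was not called, and the fibroblast list itself had an adjusted p of 0.377 with an estimated correlation.

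Of 40 cell cycle genes, 19 were higher and 0 lower with 13 libraries (24 higher when adjusted over the list alone). The kinetochore motor gene Cenpe went from 3.73 ± 2.77 to 33.7 ± 15.9 (log2 change 2.93 ± 0.35, adjusted p = 8.3e-05). Others were cyclin A2 (Ccna2, 1.76 ± 1.32 to 16.4 ± 7.42), the spindle motor Kif11 (1.18 ± 1.11 to 12.3 ± 7.93) and the checkpoint kinase Bub1b (0.903 ± 0.751 to 7.69 ± 1.62). With 16 libraries 0 of the 40 were called (17 higher when adjusted over the list alone). The list was higher in both fits with a preset correlation, at an adjusted p of 0.0156 with an estimated correlation in 16 libraries and of 0.0765 in 13. Inflammatory cytokine and adhesion genes went the same way with 13 libraries, 7 higher and 1 lower of 19 (11 and 2 when adjusted over the list alone). Examples are the chemokines Cxcl1 (1.29 ± 1.11 to 15.4 ± 3.83) and Ccl2 (2.62 ± 0.483 to 20.9 ± 11.3) and the cytokine Il6 (0.0570 ± 0.0475 to 3.32 ± 0.878). The list's adjusted p with an estimated correlation was 0.0273 with 16 libraries, where 0 members were called, and 0.114 with 13. The enzyme gene Ptgs2, which makes prostaglandin precursors, rose from 1.32 ± 1.62 to 22.3 ± 8.88.

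Of 12 macrophage and monocyte genes, 4 were higher and 1 lower with 13 libraries (9 and 1 when adjusted over the list alone), and 2 higher with 16. The integrin gene Itgam went from 0.156 ± 0.122 to 9.39 ± 5.53 and the lysosomal Cd68 from 0.766 ± 1.02 to 5.82 ± 2.55 with 13 libraries. Mrc1, a mannose receptor also made by lymphatic endothelium, was the lower member, at 90.2 in sham and 46.2 in MI. Mrc1 lost its call without MI P1 library 1 (adjusted p = 0.0518), sham P56 library 1 (0.0936), or MI P56 library 1 (0.0666), 2 (0.0741) or 3 (0.193). The macrophage list was at an adjusted p of 0.0154 with an estimated correlation in 16 libraries and of 0.0967 in 13. Secreted growth factor genes included 6 higher and 0 lower of 29 with 13 libraries (8 and 3 when adjusted over the list alone), at adjusted p of 0.0154 with an estimated correlation in 16 libraries and 0.0787 in 13. One was Hgf, hepatocyte growth factor, at 0.918 ± 0.537 in sham and 8.65 ± 0.315 in MI. Of 24 immediate early genes, 6 were higher and 0 lower with 13 libraries (8 when adjusted over the list alone), among them Myc (3.5 ± 0.365 to 12.6 ± 3.17). The list had an adjusted p of 0.0154 with an estimated correlation in 16 libraries (median 0.78) and 0.143 in 13 (median 0.54). The fit with 16 libraries includes an MI P56 library that held transcripts high in neonates, as described below. Immediate early genes were themselves higher in neonatal than in adult sham hearts (median -1.815 for P56 against P1 with 13 libraries). How far that MI P56 library accounts for the call with 16 libraries was not tested.

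Kdr, the main VEGF-A receptor (chromosome 5, 75932827 to 75978458), fell with 13 libraries from 136 ± 17.3 (n = 4) to 58.4 ± 14.5 (n = 3), a log2 change of -1.23 ± 0.23 (adjusted p = 0.0036). The water channel gene Aqp1 fell from 133 ± 29.5 to 50.0 ± 20.8. Of 23 blood endothelial genes, 4 were lower and 0 higher (10 lower and 1 higher when adjusted over the list alone). Of 18 pan-endothelial genes 5 were lower (9 when adjusted over the list alone), and 1 of 24 lymphatic identity genes was lower (4 when adjusted over the list alone). The lists had medians of -0.77, -0.67 and -0.46, and each was lower with a preset correlation. With an estimated correlation their adjusted p was 0.121, 0.0967 and 0.222 with 13 libraries, and that of the pan-endothelial list was 0.0307 with 16. In the fit with 16 libraries the lymphatic identity list lost even the preset call without sham P56 library 1 (adjusted p = 0.0517) or MI P56 library 3 (adjusted p = 0.101). Reelin (Reln), a lymphatic gene, was at 396 ± 113 in sham and 196 ± 61.8 in MI with 13 libraries and was not called (adjusted p = 0.0620).

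Of 17 cardiomyocyte genes, 12 were lower and 0 higher with 13 libraries (15 lower when adjusted over the list alone), with a median of -1.66 and an adjusted p of 0.0765 with an estimated correlation. The myosin heavy chain gene Myh6 (chromosome 14, 54941981 to 54966927) went from 213 ± 65.9 to 37.7 ± 11.9 (log2 change -2.46 ± 0.38, adjusted p = 0.0012). Ttn went from 1301 ± 382 to 345 ± 92.6 and myoglobin (Mb) from 40.0 ± 12.7 to 6.92 ± 3.17. With 16 libraries 1 of the 17 was lower (13 when adjusted over the list alone), at an adjusted p of 0.0154 with an estimated correlation. Cox6a2, a heart and muscle subunit of cytochrome oxidase outside that list, went from 9.70 ± 5.02 to 0.688 ± 0.484 with 16 libraries (log2 change -2.62 ± 0.42, adjusted p = 0.0063). Abcc9, a potassium channel subunit of pericytes and cardiomyocytes, went from 87.9 ± 45.2 to 22.2 ± 2.37 with 13 libraries. Fatty acid genes (3 of 18 lower, 5 when adjusted over the list alone, median -0.51) and interferon response genes (0 of 25 called, 3 lower when adjusted over the list alone, median -0.46) were lower as lists. Each was at an adjusted p of 0.0787 with an estimated correlation. Preset calls of the MHC, hypoxia, mesenchymal transition and imprinted lists had adjusted p of 0.185, 0.308, 0.185 and 0.270 with an estimated correlation. Lymphangiogenic signalling genes (3 higher and 3 lower of 30), matrix proteases (2 and 1 of 20), basement membrane genes (1 and 0 of 22) and pericyte genes (1 and 2 of 12) were not called as lists. Median, mean and rank differed in sign for the endocardial list in both fits, for the platelet, basement membrane, protease and sex-linked lists with 16 libraries and for the Schwann list with 13, none of them called.

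In total 23 of 13243 genes were called at P56 with 16 libraries, 19 higher and 4 lower, and 446 of 13033 with 13 libraries, 307 higher and 139 lower, 22 of them shared with the 23. Without 1 library the 23 became 110 (without sham P1 library 1), 65 (sham P1 2), 15 (sham P1 3), 13 (MI P1 1), or 14 (MI P1 3). It became 10, 13, 8 and 6 without sham P56 library 1, 2, 3 or 5 and 14, 15 and 10 without MI P56 library 1, 2 or 3. The 446 became 143 without MI P56 library 3. Of the named genes called, 6 of 14 (Tnc, Lox, Col1a1, Fn1, Spp1 and Cox6a2) kept their call without any 1 library in the fit of 16, and 37 of 59 in the fit of 13.

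**Figure D2:**
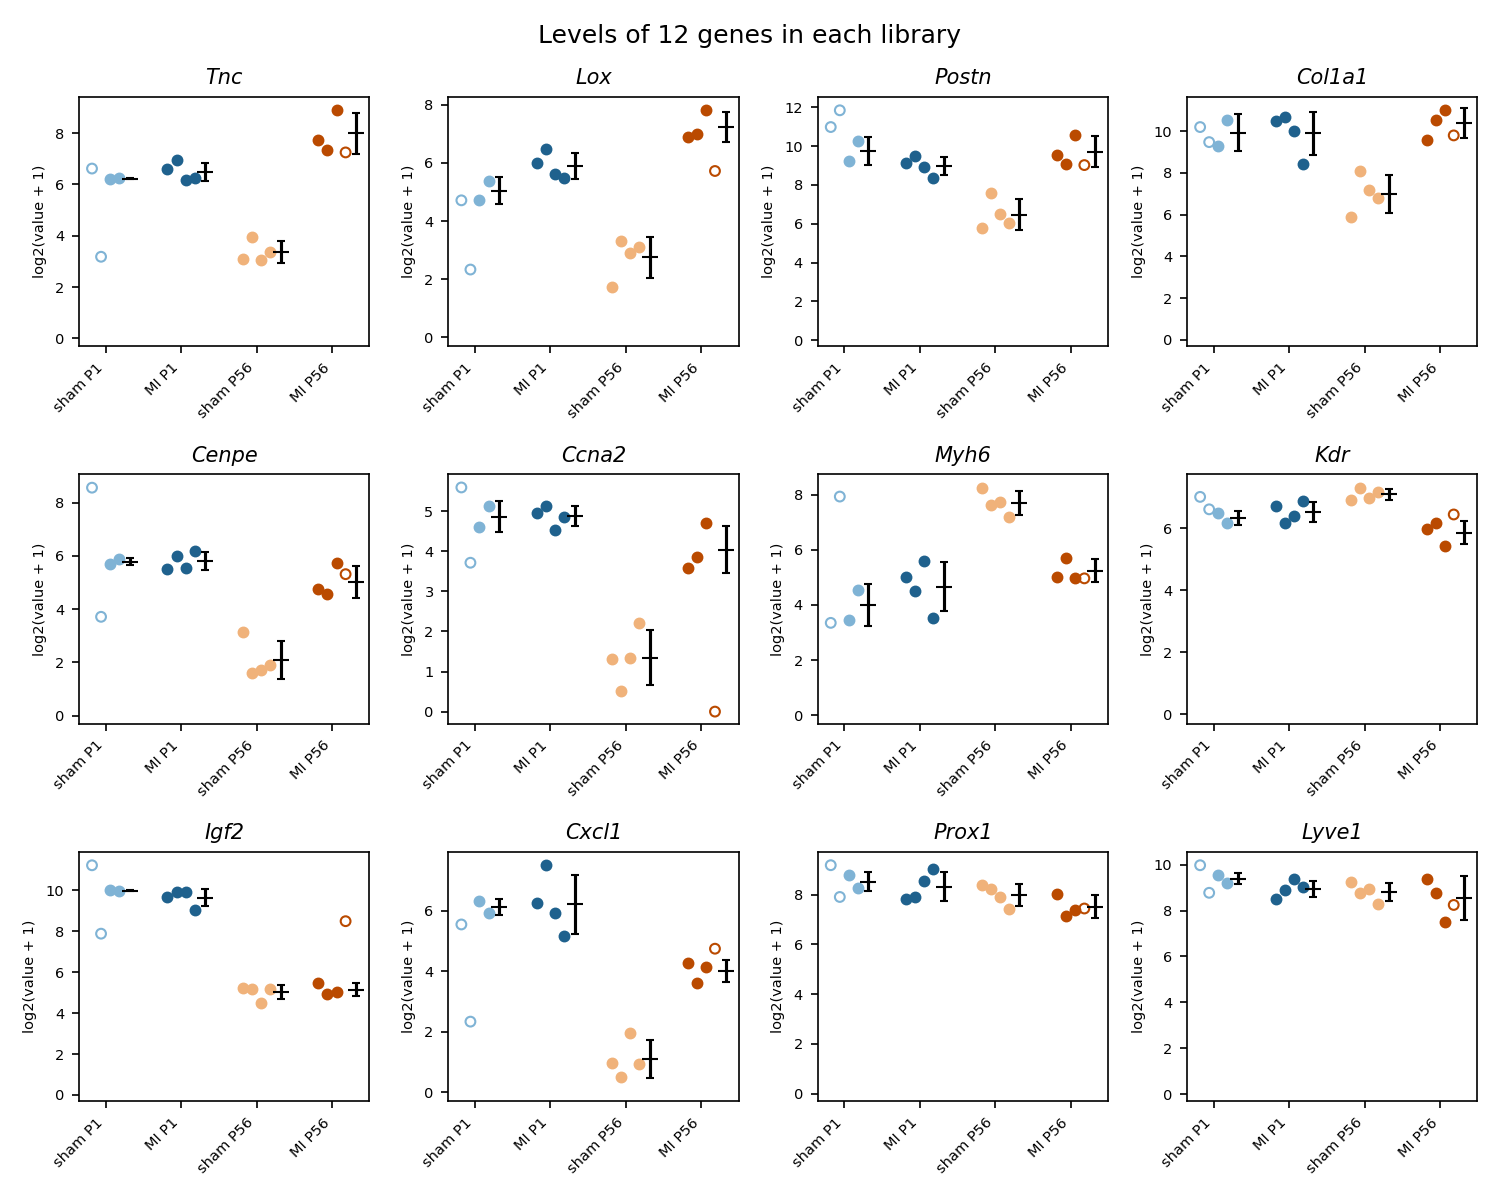
Values of 12 genes in each library as log2(value + 1) by group; open circles are the 3 libraries with few genes, and the black dash and bars are the mean and SD of the others. Tnc averages 9.70 in sham P56 and 283 in MI P56 without these libraries, and Prox1 259 and 189.

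At P1 the question is which transcripts differ after infarction of a heart that can regenerate, and no gene passed the test. The gene closest to it with 13 libraries was Enpp2 (autotaxin, which makes lysophosphatidic acid), at 6.14 ± 0.894 (n = 2) in sham and 32.1 ± 7.75 (n = 4) in MI. The log2 difference was 2.19 ± 0.34 (limma adjusted p = 0.0589). Vwf, von Willebrand factor of blood vessels, was at 1.5 ± 0.0318 and 13.6 ± 6.34 (adjusted p = 0.220), and Flt1, a VEGF receptor of blood endothelium, at 9.12 ± 6.04 and 26.3 ± 9.00 (adjusted p = 0.657). Nov, a secreted matricellular gene, was at 42.4 ± 26.9 in sham and 10.5 ± 1.97 in MI (adjusted p = 0.220), and Sema3c, a guidance factor, at 61.6 ± 34.1 and 19.6 ± 3.37. With all 16 libraries the smallest adjusted p was that of Synpo2, an actin-binding gene of muscle (0.754 ± 0.999 and 11 ± 4.06, log2 difference 2.89 ± 0.52, adjusted p = 0.0744). Col6a5, a collagen VI gene, came next (2.78 ± 3.19 and 27.6 ± 9.15). The mitochondrial complex I gene mt-Nd2 was at 41364 ± 56533 in sham and 1289.6 ± 904 in MI. Its sham mean rested on sham P1 libraries 1 and 2 (38437 and 122230), and without them it was 2392 ± 1417.

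Among lists with 13 libraries, camera placed blood endothelial genes (median 0.41, 21 of 23 positive), pan-endothelial genes (0.29), mesothelial genes (0.45) and 3 erythroid genes (0.83) higher after MI at P1, with 0 members called. The adjusted p with an estimated correlation was 0.394 for blood endothelial and erythroid genes and 0.530 for pan-endothelial and mesothelial ones, and the pan-endothelial call was lost without sham P1 library 5 (0.16, adjusted p = 0.128). Calls with a preset correlation for 6 further lists (cardiomyocyte, inflammatory, MHC, immediate early, fibroblast and mitochondrially encoded genes) were lost without at least 1 library and held in none with an estimated correlation. With 16 libraries the preset test placed the fibroblast list (median -0.70) and the lymphatic identity list (-0.29, but a higher rank and 0.17 with quantile normalization) lower and the inflammatory (0.77) and mesothelial (0.88) lists higher. The mitochondrially encoded list (median -2.27) was lower too, with 7 of 7 members lower when adjusted over the list alone, and its median was -0.55 with 13 libraries. The adjusted p of these 5 lists with an estimated correlation was 0.702, 0.648, 0.770, 0.702 and 0.454. Without 1 library, the preset call ended for fibroblast genes (MI P1 5, adjusted p = 0.0792), lymphatic identity genes (sham P1 1, 0.132) and mesothelial genes (sham P1 5, 0.0668). For inflammatory genes it ended without MI P1 library 1 (0.0516) or 2 (0.210) or sham P1 library 1 (0.166) or 5 (0.10). Quantile normalization ended the preset call of the fibroblast (-0.19, adjusted p = 0.912), lymphatic identity (adjusted p = 0.790) and mitochondrially encoded lists (-0.15, adjusted p = 0.374). The median of all genes was 0.39 in this fit of 16 libraries, and 7 lists (cardiomyocyte, pericyte, lymphangiogenic, interstitial matrix, protease, interferon and MHC genes) had a positive median but a lower rank than other genes. The cardiomyocyte median of 0.46 lay above that of all genes, while the mean of this list was 0.19. The immediate early list had a median of -0.07 and a mean of 0.13. With 13 libraries the sex-linked list had a median of 0.05 and a lower rank. Cell cycle genes (median -0.16 with 13 libraries and 0.60 with 16) and interstitial matrix genes (-0.08 and 0.28) were not called at P1 in either fit. With quantile normalization of the 16 libraries the preset test called the matrix list higher. With 13 libraries the sign of its median depended on which sham P1 library was left out.

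By limma, 0 genes passed in either fit, with 1586 at an unadjusted p under 0.05 with 16 libraries and 485 with 13, where chance gives 662 and 652. On the recovered reads edgeR called 0 in both fits and DESeq2 called 262 and 7, and limma with weights per library called 70 and 8. The 0 with 16 libraries became 3 without sham P1 library 3, 1 without MI P56 library 1 and 3 without MI P56 library 5. That with 13 became 2 without sham P56 library 2, 1 without sham P56 library 5, 2 without MI P56 library 1 and 1 without MI P56 library 2.

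Whether the response differs between ages was tested by the interaction, positive where the log2 change after MI was higher at P56 than at P1. With 13 libraries Tnc was at 73.7 ± 0.937 (n = 2) in sham and 91.0 ± 22.7 (n = 4) in MI at P1, against 9.70 ± 3.37 and 283 ± 168 at P56. The difference was 4.35 ± 0.47 on the log2 scale (limma adjusted p = 2.2e-04), and Tnc kept its call without any 1 library. Postn was at 909 ± 442 and 522 ± 160 at P1 and at 98.2 ± 61.3 and 928 ± 524 at P56 (4.02 ± 0.61, adjusted p = 0.0057). Lox differed by 3.62 ± 0.52 (adjusted p = 0.0054). Anln, an actin-binding gene of cell division, differed by 3.21 ± 0.49 (39.0 ± 17.9 and 27.1 ± 3.20 at P1, 3.53 ± 1.77 and 28.8 ± 8.87 at P56). Enpp2 went the other way, at 6.14 ± 0.894 and 32.1 ± 7.75 at P1 and at 24.6 ± 8.04 and 12.7 ± 6.32 at P56 (-3.14 ± 0.46, adjusted p = 0.0054). So did Btnl9, a butyrophilin-like gene of capillary endothelium (-2.87 ± 0.38, adjusted p = 0.0023). Without sham P1 library 5 the calls of Postn (3.51, adjusted p = 0.147), Lox (3.30, 0.10), Anln (2.74, 0.161), Enpp2 (-3.01, 0.0942) and Btnl9 (-2.49, 0.0914) were lost. With 16 libraries Postn was the gene called (4.68 ± 0.71, adjusted p = 0.0155). It was above the threshold without sham P1 library 1 (0.0662), MI P1 3 or 5 (0.0567, 0.0708), sham P56 1, 3 or 5 (0.0751, 0.0540, 0.0717) or MI P56 1 or 3 (0.0538, 0.0629).

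By list, 6 of 40 cell cycle genes were higher in the interaction with 13 libraries and 0 lower (21 when adjusted over the list alone, median 1.37). Also higher were 5 of 29 interstitial matrix genes (22 when adjusted over the list alone, median 1.71) and 2 of 14 fibroblast genes (5 when adjusted over the list alone). Of 17 cardiomyocyte genes 3 were lower (14 when adjusted over the list alone, median -1.79), and of 23 blood endothelial genes 1 was lower (11 when adjusted over the list alone, median -1.23). With an estimated correlation in 13 libraries, the adjusted p was 0.0670 for cell cycle, cardiomyocyte and blood endothelial genes, 0.113 for matrix and 0.323 for fibroblast genes. With 16 libraries 0 cell cycle genes were called, over all genes or over the list alone (median 0.57). In the matrix and fibroblast lists 1 gene each was higher (10 and 5 over the list alone, medians 1.33 and 1.17). No cardiomyocyte or blood endothelial gene was called (6 lower in each over the list alone, medians -1.98 and -1.38). No list call held with an estimated correlation in the interaction, the smallest adjusted p being 0.0669 with 16 libraries (immediate early genes, median 0.80) and 0.0670 with 13. In the fit of 16 libraries 8 lists had a negative median and a higher rank than other genes, of which the inflammatory and growth factor lists had a positive mean. With 13 libraries the basement membrane list had a median of 0.00 and a mean of -0.12.

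With 13 libraries 63 genes were called in the interaction, 42 higher and 21 lower, against 1 with 16 libraries. Leaving out 1 library turned the 63 into 15 and 1 (sham P1 3 and 5), or 6, 40, 11 and 33 (MI P1 1, 2, 3 and 5). It also gave 228 and 28 (sham P56 2 and 5) and 30 and 7 (MI P56 1 and 3). The 1 became 2 without sham P1 library 2. Across 13033 genes, which are not independent replicates, the responses at both ages correlated with r of -0.02. Of 307 genes higher after MI at P56, 158 had a positive change at P1, with a median of 0.02 there. With 16 libraries r was 0.10, and of 19 genes higher at P56, 18 had a positive change at P1, with a median of 0.93 where that of all genes was 0.39.

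Between sham hearts of both ages the comparison shows what distinguishes adult from neonatal cells apart from infarction, together with the digestion, pooling and sex that go with age. Igf2, insulin-like growth factor 2 (chromosome 7, 142650766 to 142666816), was at 1156 ± 894 (n = 4) at P1 and 32.3 ± 7.11 (n = 4) at P56 with 16 libraries (log2 change -4.73 ± 0.65, limma adjusted p = 2.8e-04). H19, its neighbouring imprinted RNA, was at 246 ± 114 and 4.77 ± 2.80 (-5.39 ± 0.70). Top2a, topoisomerase II of dividing cells, was at 105 ± 57.3 and 7.55 ± 3.45 (-3.51 ± 0.50), and the adhesion gene Sele (E-selectin) at 42.7 ± 23.5 and 0.528 ± 0.761. Xirp2, an actin-binding gene of cardiomyocytes, was at 1.71 ± 1.66 and 51.4 ± 21.4 (4.38 ± 0.54) and the troponin gene Tnni3 at 1.04 ± 1.13 and 17.9 ± 7.42. Xist, the RNA that silences 1 X chromosome in females, was at 977 ± 974 at P1 and 0.869 ± 0.470 in the male adults.

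Of 17 imprinted and fetal growth genes, 7 were lower with 16 libraries (8 when adjusted over the list alone) and 12 with 13 (14 when adjusted over the list alone), 0 being higher. Of 40 cell cycle genes 9 were lower with 16 libraries (17 when adjusted over the list alone) and 31 with 13 (36 when adjusted over the list alone). Of 24 immediate early genes, which dissociation of tissue also raises, 10 were lower with 16 libraries (15 when adjusted over the list alone) and 16 with 13 (18 when adjusted over the list alone). These 3 list calls held with an estimated correlation in both fits (adjusted p = 0.0286 and 0.00995, 0.0446 and 0.0143, 8.9e-04 and 0.0143). Examples with 13 libraries are Mest (253 ± 60.8 to 23.4 ± 17.1), Cenpe (54.5 ± 5.09 to 3.73 ± 2.77) and the stress transcription factor Atf3 (46.9 ± 1.53 to 3.84 ± 2.82). Of 29 interstitial matrix genes 13 were lower with 13 libraries (17 when adjusted over the list alone), among them Fbn2, a fibrillin of developing tissue (27.2 ± 9.47 to 0.663 ± 0.493), and Fn1 (839 ± 113 to 123 ± 37.1). Of 19 inflammatory genes 7 were lower and 1 higher (11 and 2 when adjusted over the list alone). The adjusted p with an estimated correlation was 0.290 for matrix and 0.213 for inflammatory genes.

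Higher at P56 were 16 of 17 cardiomyocyte genes with 13 libraries (17 when adjusted over the list alone), 14 of 25 interferon response genes (15 when adjusted over the list alone) and 5 of 12 MHC genes (8 when adjusted over the list alone), each with 0 lower. The adjusted p was 0.0332, 0.00702 and 0.0143 with an estimated correlation. With 16 libraries 10, 5 and 3 members were higher, and the adjusted p with an estimated correlation was 0.0521, 0.0941 and 0.226. The antiviral sensor Ifih1 went from 1.53 ± 0.497 to 14.5 ± 5.83 and Ifit1 from 0.704 ± 0.131 to 11.4 ± 1.77. Blood endothelial genes were higher in 13 of 23 and lower in 0 (15 when adjusted over the list alone), at an adjusted p of 0.0673 with an estimated correlation. Flt1 was at 9.12 ± 6.04 and 74.7 ± 28.0, Aqp1 at 27.2 ± 3.72 and 133 ± 29.5 and the fatty acid transporter Cd36 at 30.3 ± 4.01 and 195 ± 78.8. Of 24 lymphatic identity genes 6 were higher and 1 lower, and the list was not called (median 0.01, adjusted p = 0.424 by camera).

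With 16 libraries 518 genes were called between ages in sham, 334 higher and 184 lower at P56, and with 13 libraries 1716, 767 higher and 949 lower, sharing 459. Without 1 library the 518 became 946 and 796 (sham P1 2 and 3), 344 and 345 (MI P1 1 and 2) or 874 (MI P56 5). It became 272, 245, 203 and 207 without sham P56 library 1, 2, 3 or 5. The 1716 became 804 and 644 without sham P1 library 3 or 5, which leaves 1 sham P1 library whose spread is assumed to be that of the other groups. Under quantile normalization, which moved the median of all genes by -0.39, 47.8% of called genes were higher instead of 64.5%. On the recovered reads of the 16 libraries more genes were lower than higher at P56, 990 and 393 by edgeR and 1006 and 660 by DESeq2. The sex-linked list had a positive median (0.68 and 1.04) and a negative mean (-0.89 and -0.67) in the 2 fits, as Xist was lower and Y-linked genes higher. With 16 libraries 9 other lists, none called, differed in sign between median, mean and rank (lymphatic identity, endocardial, macrophage, platelet, Schwann, lymphangiogenic, basement membrane, protease and hypoxia genes), and with 13 the macrophage, Schwann and hypoxia lists did.

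**Figure D3:**
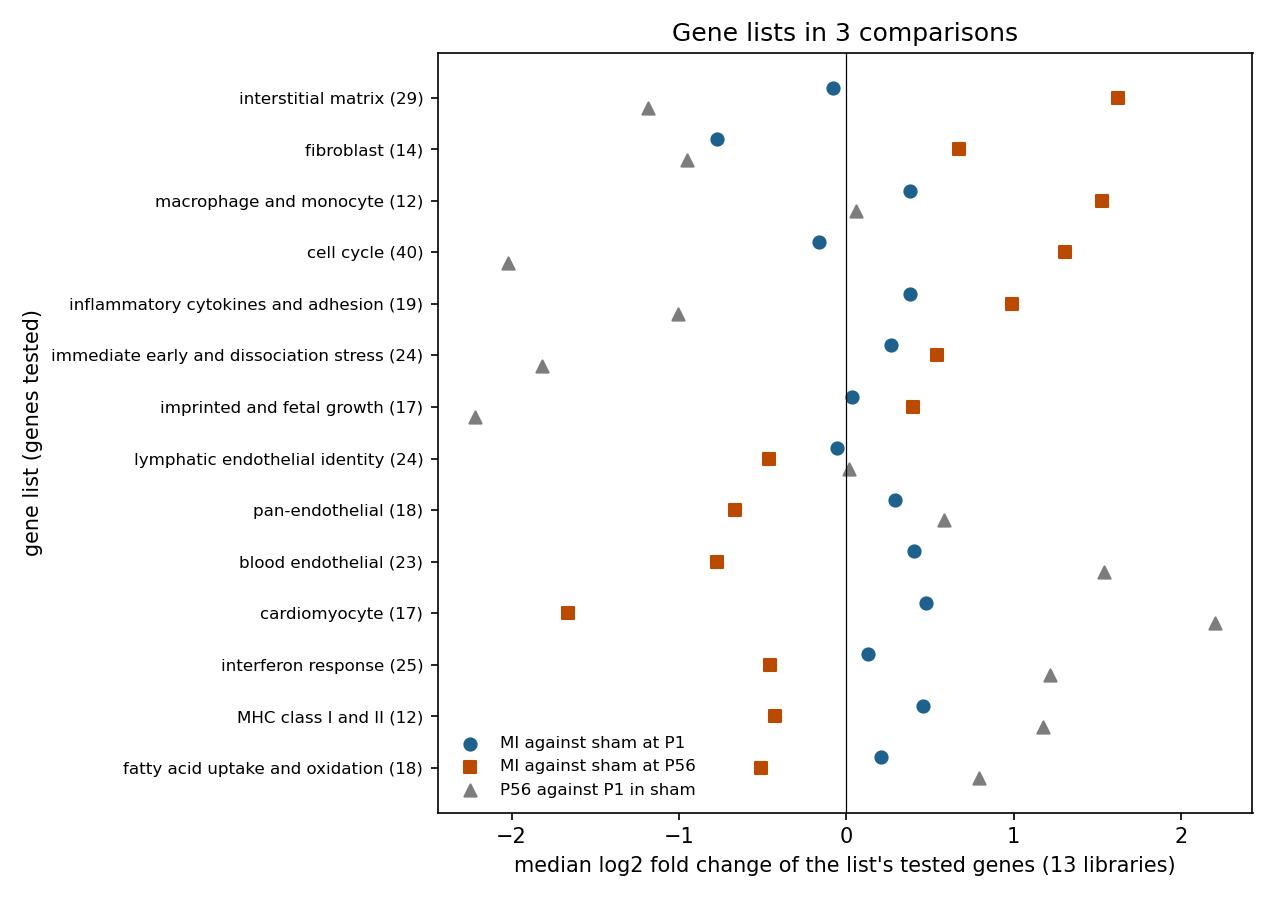
Median log2 change of 14 gene lists with 13 libraries for MI against sham at P1, MI against sham at P56, and P56 against P1 in sham. The cell cycle list stands at -0.16, 1.31 and -2.02 and the cardiomyocyte list at 0.48, -1.66 and 2.21.

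After MI, P56 and P1 hearts were compared to see which age differences stand beside an infarct. Col8a1, a short-chain collagen of vessel walls (chromosome 16, 57624258 to 57754737), was at 42.5 ± 21.5 (n = 4) at P1 and 814 ± 337 (n = 3) at P56 with 13 libraries (log2 change 4.29 ± 0.56, limma adjusted p = 1.2e-04). The lubricin gene Prg4 was at 9.23 ± 3.85 and 195 ± 133 (4.15 ± 0.42). Apod, a lipid carrier of fibroblasts, was at 0.444 ± 0.371 and 33.4 ± 12.0 (4.54 ± 0.47) and the complement gene C7 at 1.49 ± 0.950 and 43.0 ± 24.9. Igf2 was lower, at 815 ± 205 and 35.0 ± 7.63 (-4.48 ± 0.24). Also lower were H19 (339 ± 38.7 and 10.6 ± 3.77), Sele (51.8 ± 22 and 1.15 ± 0.344) and the immediate early gene Fosb (391 ± 130 and 19.5 ± 9.61). All 8 kept their call without any 1 library in this fit. With 16 libraries they were called too, with Col8a1 at 3.89 ± 0.75 and Igf2 at -3.65 ± 0.65, and each lost its call without at least 1 library.

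Of 24 immediate early genes 15 were lower at P56 after MI with 13 libraries and 0 higher (21 when adjusted over the list alone, median -1.35). Of 17 imprinted and fetal growth genes 11 were lower (13 when adjusted over the list alone, median -1.63). Interferon response genes were higher in 8 of 25 and lower in 0 (12 and 1 when adjusted over the list alone, median 0.65), such as Ifit3 (0.227 ± 0.165 to 3.67 ± 0.582). These 3 lists had an adjusted p of 0.00704 each with an estimated correlation. With 16 libraries the adjusted p of immediate early genes was 0.0102, that of imprinted genes 0.0141 and that of interferon genes 0.111 with an estimated correlation. Of 40 cell cycle genes 6 were lower (14 when adjusted over the list alone, median -0.78, adjusted p = 0.165 with an estimated correlation). Cardiomyocyte genes (1 of 17 higher, median 0.15) were not called as a list. Interstitial matrix genes were 4 higher and 3 lower of 29, with the cross-linking enzyme Loxl3 higher (2.81 ± 1.21 to 20.7 ± 10.3). Their preset call was lost without MI P1 library 5 (adjusted p = 0.293) or MI P56 library 3 (0.436), at an adjusted p of 0.670 with an estimated correlation. Signs of median, mean and rank differed with 16 libraries for the blood endothelial, lymphangiogenic, hypoxia, mitochondrially encoded and sex-linked lists and with 13 for the lymphangiogenic, protease, fatty acid and sex-linked lists, none of them called.

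With 16 libraries 14 genes were called between ages after MI, 7 higher and 7 lower, and with 13 libraries 697, 272 higher and 425 lower, which include the 14. Without 1 library the 14 became 104 and 49 (sham P1 1 and 2), or 0, 3, 0 and 6 (MI P1 1, 2, 3 and 5). It became 9 and 7 without sham P56 library 2 or 5 and 2, 1, 0 and 28 without MI P56 library 1, 2, 3 or 5. The 697 became 464 (MI P1 5), 1344 (sham P56 2), or 449 and 317 (MI P56 1 and 2). With 13 libraries the genes called in sham and after MI shared 149 of those higher at P56 and 281 of those lower. Independent lists of the same sizes would share 16 and 30.9, although the neonatal and adult libraries differ in the same technical ways in both.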

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

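The tests on mixed or mislabelled libraries, on the cell types behind the adult response and on digestion time were chosen after the results were seen, as was the fit with 13 libraries, while the splits were planned and were applied to that fit when it was added.

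Genes whose response to MI differed between ages, by the interaction on the log2(value + 1) scale, were Postn with all 16 libraries (4.68) and 63 genes with 13 libraries, of which the 6 with the largest change in each direction at a mean of at least 5 are given here. The change after MI was higher at P56 than at P1 for Tnc (4.35), Postn (4.02), Cthrc1 (3.67), Lox (3.62), Col12a1 (3.41) and Anln (3.21). At P1 the means of Postn and Anln were lower in MI than in sham. Enpp2 (-3.14), Myh6 (-3.13), Actc1 (-3.05), Dsp (-2.97), Btnl9 (-2.87) and Mcf2l (-2.67) were on the other side. The first group holds 4 of the 29 interstitial matrix genes and the second 2 of the 17 cardiomyocyte genes (Myh6 and Actc1), lists at adjusted p of 0.113 and 0.0670 with an estimated correlation in the interaction. Of these 12, Tnc kept its call without any 1 library, and each of the others was lost at least without sham P1 library 5, where 1 sham P1 library remains, at 3.51 for Postn (adjusted p = 0.147) and 3.30 for Lox (adjusted p = 0.10).

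A library stood far from the rest of its group of 4 in 17 of the 160 groups of values tested, where chance gives about 1 in 20 or 8, and 12 of the 17 were in the 3 libraries with few genes. The measure is the gap to the nearest library as a share of the group's range, compared with Dixon's critical value for 4 samples. In sham P1, library 2 stood apart for Tnc (0.881, at a value of 8.08), H19 (0.838, at 80.8) and Sele (0.906, at 8.08), and library 1 for Pdpn (0.899, at 70.6) and Thy1 (0.965, at 5.26). In MI P56, library 5 did for reads (0.966), genes with a read (0.970), the share of Uqcrc1 (0.991), Xist (0.941, at 272), Igf2 (0.843, at 358), Sele (0.877, at 21.6) and Thy1 (0.881, at 4.31). In sham P56, library 2 had the most reads (0.897, 20914864) and the fewest genes with a read (0.889, 14121) and stood apart for Tmem255a (0.872, at 2.43). Library 5 held 1 read of Cthrc1 (1, at 0.0170) where the other 3 held none, which sets the ratio to 1 at any value and says nothing about that library, and library 3 was low for Igf2 (0.906, at 21.7).

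The share of splits of the libraries that gave as many genes as the real groups was counted. For MI against sham at P56, 1 of the 35 splits, the real one, gave as many (23 genes, highest other 0). With 13 libraries this was again 1 split (446 genes, highest other 109). The same held for P56 against P1 in sham (518 genes, highest other 19, 1 split) and after MI (14 and 0 with 16 libraries, 697 and 11 with 13, 1 split each). A share of 1 in 35 is the smallest these splits can give, so they argue against chance without excluding it. No splits were made for the interaction or for age in sham with 13 libraries. For the interaction 3 of 100 splits drawn gave as many as the real 1, the highest other being 1, and although this share is under 0.05, chance is not firmly excluded by a count of 1 gene over so few draws. For MI against sham at P1 the count decides nothing, since with 0 genes called each of the 35 splits gives as many (highest other 0).

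The library labelled MI P56 5 held transcripts that are high in neonates, with Xist (272), Igf2 (358) and H19 (190) far above the means of the other MI P56 libraries (1.72, 35.0 and 10.6). A whole neonatal library under this label is argued against, since genes higher in adults placed its neonatal share at 0.467 (95% interval 0.269 to 0.725), while the neonatal libraries with many genes lay between 0.950 and 1.1 on this measure. Reads of several libraries in 1 remain a candidate explanation, as genes higher in neonates gave a share of 0.601 (0.499 to 0.728), between the adult libraries (-0.0402 to 0.0714) and the neonatal ones (0.793 to 1.27). The test was changed to this set alone after the adult-high genes were seen to spread from -0.767 to 0.758 among good adult libraries. The 31 neonatal-high and 15 adult-high genes were chosen by their age difference in the same 13 libraries that gave these ranges. The ranges are therefore apart by construction, and a library outside that choice can fall between them for this reason too. MI P56 library 5 held 680 reads on these genes, and the intervals resample genes without counting error. For sham P1 library 2, with Myh6 at 242, a whole adult library is argued against by a share of 1.01 (0.969 to 1.03), whereas a mixture and a purely neonatal library cannot be told apart at a share of 1.38 with an interval of -0.0139 to 5.41, and no biological explanation was tested for either library.

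After MI at P56, 17 of 29 matrix, 4 of 12 macrophage and 19 of 40 cell cycle genes were higher with 13 libraries, although the lists themselves had adjusted p of 0.0967, 0.0967 and 0.0765 with an estimated correlation. A lower share of lymphatic endothelial cells in the sort, with the other cells in unchanged proportions, is argued against as the whole cause. It would raise the markers of every other cell type, and 12 of 17 cardiomyocyte genes fell with an upper quartile of -1.12. Of the 6 cell type lists examined for this the fibroblast and macrophage medians were positive (the 3 erythroid genes, at a median of 0.90, were not among them). The test cannot exclude a lower share together with a change among the other cells. With 13 libraries 1 of 24 lymphatic identity and 0 of 18 pan-endothelial genes had a positive change (medians -0.46 and -0.67). More fibroblasts like those of sham hearts are argued against too: 10 fibroblast genes outside the matrix list, among them the abundant Dcn (738 in sham, 613 in MI), had a median of 0.40 (upper quartile 0.71), against 2.86 (lower quartile 2.43) for the 4 inside it. Fibroblasts of an activated kind and leukocytes that pass the CD45 gate (Ptprc at 3.21 after MI and 0.939 in sham) stay open. So do fewer cardiomyocyte fragments in the sort after MI, of untested cause, and a change within the lymphatic cells themselves. The sort is meant to leave out fibroblasts and leukocytes, but how far it did was not measured, and podoplanin is also found on fibroblasts of injured tissue. The response to infarction is the biological difference that the design names.

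Immediate early genes were higher at P1 than at P56 in sham and after MI alike. Neonatal hearts were minced and digested for longer, which could raise these genes, and the list's median of -1.35 after MI with 13 libraries goes with that. The digestion and the age cannot be told apart, because every neonatal library had the one and every adult library the other. Age, pooling and sex of the animals also stay open, as untested.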

How the results depend on the processing

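The fit with 13 libraries, the alternatives applied to it and the fit of the 12 numbered libraries without a block were chosen after the data were seen, and the other alternatives were planned.

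Counts of called genes are given in the order MI against sham at P1, MI against sham at P56, interaction, age in sham and age after MI, with 0, 23, 1, 518 and 14 for 16 libraries and 0, 446, 63, 1716 and 697 for 13. Without the filter on low values and with median-of-ratios rescaling all 5 counts stayed within 1.5 times those of 16 libraries. A pseudocount of 0.25 gave 0, 10, 1, 362 and 1, and one of 4 gave 0, 42, 0, 534 and 13. A value of at least 5 in 4 libraries gave 12 at P56 and 7 for age after MI. Quantile normalization gave 2, 122, 0, 927 and 122, and moved the median of all genes by -0.46, 0.14, 0.57, -0.39 and 0.16; median-of-ratios moved that of the interaction by 0.11. Weights per library gave 70, 899, 438, 3053 and 1419, with weights of 0.0598, 0.113 and 0.147 on the 3 libraries with few genes. A fit of only the groups compared gave 82 at P56, 32 for age in sham and 220 for age after MI. With edgeR the counts were 0, 39, 1, 1383 and 14, and with DESeq2 262, 175, 107, 1666 and 107. For age in sham they held 393 higher and 990 lower genes with edgeR and 660 and 1006 with DESeq2, against 334 and 184 with limma. Without the 3 libraries with few genes they are those of 13 libraries. Leaving out 1 library of 16 gave 0 to 3, 6 to 110, 0 to 2, 203 to 946 and 0 to 104. The cause of these changes was not tested, except that fewer genes are tested under the stricter value and fewer samples enter the smaller fits.

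The replicate number as a block in limma, possible for the 12 libraries whose number matches a label, gave 0, 0, 0, 127 and 6, and the same 12 without the block 0, 5, 0, 175 and 9. Over all groups the numbers showed little pairing: across 18 pairs with the same number the mean correlation of residuals was 0.00912 (-0.109 to 0.101) against -0.00409 for other pairs. Of 12 libraries, 7 matched best with their own number. Between sham P56 and MI P56, pairs with the same number were at 0.101, 0.0478 and 0.0866, and the others at -0.0653 to -0.0129. Residuals were centred within each group, so positive values in some pairs push the other pairs below 0, and the contrast adds little. A pairing of the adult libraries is neither shown nor excluded.

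In the fit with 13 libraries, P1 gave 2 with a pseudocount of 0.25, 2 with quantile normalization, 8 with weights and 7 with DESeq2. Weights gave 768, 317, 2766 and 1365 for the others, DESeq2 866 at P56 and 324 for the interaction, and a pseudocount of 4 gave 34 for the interaction. Leaving out 1 library gave 0 to 2, 143 to 645, 1 to 228, 644 to 2270 and 317 to 1344; the cause was not tested.

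Some lists ranked on the other side of all genes under an alternative, in places with a median that kept its sign. The estimated correlation was computed only in the fits of 16 and 13 libraries. None of these lists was called with it there in the comparison concerned. The calls below are those of camera with a preset correlation. With 16 libraries at P1, the rank of these lists turned from lower to higher. Quantile normalization put the median of lymphatic identity at 0.17, interstitial matrix at 0.75, proteases at 0.42 and immediate early genes at 0.30. Weights put pericyte genes at 0.44, cardiomyocyte genes at 0.69, MHC genes at 0.32 and immediate early genes at 0.26, and the fit of 13 libraries put cardiomyocyte genes at 0.48, MHC genes at 0.46 and immediate early genes at 0.27. Lymphatic identity lost its call with quantile normalization. The other lists were not called with 16 libraries and were called higher under the alternative named. With 13 libraries their adjusted p by camera was 0.0043 (cardiomyocyte), 0.020 (MHC) and 0.020 (immediate early). Cell cycle genes, not called at P1 in either fit, turned from a higher rank (median 0.60 with 16 libraries) to a lower one (-0.16 with 13). For the interaction, lymphatic identity turned from a higher to a lower rank, with a median of -0.28 with 16 libraries, -0.74 with quantile normalization and -0.43 with 13 libraries. It was not called with 16 libraries and was called lower under both alternatives (adjusted p = 0.0139 by camera with 13 libraries). Mitochondrially encoded genes also turned from a higher to a lower rank with quantile normalization, from 1.72 to -0.48. With 13 libraries, leaving out 1 library put interstitial matrix at -0.42 (sham P1 3) to 0.28 (sham P1 5) at P1. Each of these 2 fits keeps 1 sham P1 library, so the direction of this list at P1 depends on which one is kept. No named gene that was called in the fit itself or in an alternative changed side between them, and the sign of genes called in neither was not compared. Depth limits what can be seen in the 3 libraries with few genes, where 1 read is worth up to 4.31.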

Other observations

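The test of the adult response against the neonatal level was chosen after the data were seen. Further genes that differed between sham P1 and sham P56 are given here with 13 libraries. The sorts also held transcripts of other cell types, and age is tied to the digestion, surgery, pooling and sex. These values therefore need not describe the lymphatic cells. Nr1d1, a repressor of the circadian clock, was at 2.41 ± 1.87 (n = 2) in sham P1 and 42.2 ± 22.5 (n = 4) in sham P56 (log2 change 3.61 ± 0.48, limma adjusted p = 6.4e-05), and the time of day of harvest was not analysed here. The basement membrane chains Col4a3 and Col4a4 were at 1.11 ± 0.850 and 2.47 ± 0.210 in sham P1 and at 14.4 ± 6.26 and 17.4 ± 7.25 in sham P56, and without sham P1 library 5 Col4a3 was no longer called (2.40, adjusted p = 0.0757). The pericyte gene Rgs5 was at 112 ± 62.4 and 638 ± 266 in the same groups (2.52 ± 0.42).

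Male and female transcripts were both present in the neonatal pools. Xist averaged 613 in sham P1 and 678 in MI P1, where the Y-linked Kdm5d was at 9.86 and 9.70, Uty at 12.7 and 10.3 and Eif2s3y at 8.46 and 8.61. In the adults Xist was at 0.869 in sham and 1.72 after MI and these Y-linked genes between 21.4 and 28.9, as in males.

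A hypothesis from these data is that MI may move the adult profile towards the neonatal level, since 19 of 40 cell cycle genes were higher after MI at P56 (list median 1.31, adjusted p = 0.0765 with an estimated correlation) and 31 of 40 lower in adult than in neonatal sham (list median -2.02). Across 13033 genes the change after MI at P56 and the difference of sham P1 from sham P56 were compared with different sham P56 libraries in each, in all 6 assignments. The lowest covariance was 0.192 and the highest 0.246, with correlations of 0.291 to 0.453, all above 0 as the hypothesis needs. With shared controls the covariance was 0.311 and the correlation 0.608, while 100 simulations of unchanged groups gave means of 0.0612 and 0.379. The simulations drew each gene independently, so they cannot say how large a covariance genes that vary together would give. The 6 assignments reuse the same MI P56 and sham P1 libraries, so their values are not independent. A difference shared by all sham P56 libraries would also keep these values above 0, so the test cannot tell it from a move towards the neonatal level. Genes are not independent replicates. The imprinted and fetal growth list went towards the neonatal side too, with 14 of 17 genes positive after MI at P56. Its median of 0.40 was small beside the -2.22 for age, where the cell cycle list stood at 1.31 and -2.02. The change was thus not of the same size in all lists, and a shift of the whole profile was not tested. A change in the mix of sorted cells stays open, with more dividing and matrix-producing cells in injured adult and in neonatal hearts or fewer transcripts of other cells, since cardiomyocyte genes (medians of -1.66 after MI at P56 and 2.21 for age) and blood endothelial genes (-0.77 and 1.54) also add to the covariance.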
